A study of Homo sapiens with 4 samples.

How the data were processed

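Poly(A) or other RNA selection was not given in the sources used here; per the labels' protocols, total RNA from Huh7 cells was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit. Huh7 is an established human hepatocellular carcinoma line. The 4 libraries form 2 groups by their titles: cells with a short hairpin RNA against NUP210 (shNUP210, 2 libraries) and control cells (shCon, 2 libraries), which the labels give the genotype wild type and the titles name as a control hairpin. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicate variance was above counting noise in both groups (2.61 and 2.5 times the counting variance, against 4.54 to 5.34 times between groups), so no library was treated as a copy of another.

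The authors deposited 1 table per library, and its values are TPM, an expression unit normalised for transcript length and library total. The unit was read from the column totals, which lie between 999992.7 and 999997.8. Per the submitters' processing notes, Trimmomatic, STAR, RSEM and DESeq were used with the hg38 build, with no versions or roles given, and the annotation release is not given in the sources used here. Each table lists the same 20226 genes, 5 of them at 0 in every library. Gene positions and exon overlaps were taken from GENCODE release 29 on GRCh38, which holds 19460 of the listed gene identifiers. Transcript length and GC content were averaged over the transcripts each table lists for a gene, from the release 29 sequences, and were available for 19643 genes. Current symbols were found for 19363 genes.

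TPM keeps no read depth. Among genes with a single listed transcript, the low values cluster near 0.53 to 0.67 TPM for a 1 kb transcript, which is taken as the worth of 1 fragment (0.59 and 0.67 in the shNUP210 libraries, 0.53 in both shCon libraries). At that worth, 5 TPM on a 1 kb transcript is about 7.5 to 9.4 fragments. These figures are approximate, so no counting intervals are given. The tables list no gene with a mitochondrial (MT-) symbol. Reads of mitochondrial type sit on 10 nuclear pseudogenes such as MTATP8P1 and take 6.95 to 8.9% of TPM, and values of genes within such families, and of paralogs in general, depend on how reads were shared out.

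The test design, the naming rule and 42 gene lists were fixed before the data were examined, and the design assumed expected counts, which the tables do not hold. The test used is limma (version 3.58.1, R 4.3.3) on log2(TPM + 1) with a mean-variance trend in eBayes. This had been listed as an alternative for TPM tables, on genes passing a count filter that TPM cannot give. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested, and a call is an adjusted p under 0.05. A fold change is on the log2(TPM + 1) scale, which understates changes of low genes. With 2 libraries per group, a permutation test could not give a p below 0.33, so none was used.

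The scaling and the expression filter of the main test were chosen after counts of calls had been seen. The first setting tried scaled the libraries by a trimmed mean (30% trimmed from each end) and kept genes with at least 1 TPM in 2 libraries, and it called 157 genes. With that filter, the TPM as deposited gave 57 calls, and the other scalings gave 149 (median ratio), 199 (upper quartile) and 102 (quantile). TPM without further scaling were then taken as the main values, as in the planned TPM alternative. For these, no filter gave 15 calls and a filter of 1 TPM in all 4 libraries gave 320. The main filter was then set to at least 5 TPM in 2 libraries, which gave 290 calls among 10140 genes. Its grounds are that 5 TPM on a 1 kb transcript is close to the 10-count rule of the planned filter, but it was not blind to the counts of calls.

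Of the 42 gene lists, 40 had at least 3 tested members. They were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Camera asks whether a list's members move relative to all other genes. Members were also counted at the adjusted p over all genes and adjusted over the list alone. A further 4 lists were written after the calls had been seen, and the closing section gives their counts with no test. Named genes follow a rule: NUP210, SMARCB1, EP300 and MEF2C, the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, at least 5 TPM in the higher group (in place of the scaled CPM planned) and no overlap between groups, and up to 3 examples per list with 3 or more calls and 1 in the other direction. Since many of the top folds fell on pseudogenes and antisense RNAs, the 8 highest and 8 lowest protein-coding genes without an exon overlap of 100 bases or more, and with at least 1 TPM in both groups, were added after their values were seen. Other list members named as examples were also chosen after their values were seen.

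The fit was tested on 10 simulated data sets with these libraries' mean TPM, the fragment worths above and a dispersion of 0.03, each with 200 changed genes. It recovered 29.5% of 2-fold and 95.4% of 4-fold changes, 5.4% of calls were false and 0 had the wrong sign. The changed genes were drawn from those with a mean of 10 TPM or more, and as many rose as fell. Of the genes tested in the real libraries, 2724 had a mean under 10 TPM. The real folds also had a median of 0.23, a shift that was not simulated. These rates therefore hold for the simulated setting and do not carry over to the real calls. Camera found 10 of 10 changed lists and 0 of 10 unchanged lists. In each changed list every gene rose 2-fold, and genes were simulated independently, with no shift of the fold by abundance. The list result therefore does not bear on real lists, whose members may be correlated, mixed in direction or unlike other genes in abundance. An earlier run at a dispersion of 0.01 recovered more of the 2-fold changes, and the dispersion was raised to lie nearer the spread of the real replicates.

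The alternatives tried were other scalings (median ratio, upper quartile, trimmed mean, quantile), filters, pseudocounts of 0.1 and 5, a robust variance prior, no mean-variance trend, removal of each library's length and GC trend by loess (span 0.5), the replicate number as a block, an adjusted p of 0.01 and leaving out each library in turn. Tables were joined in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.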

Results

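RNA sequencing compared Huh7 liver cancer cells with a hairpin RNA against NUP210, which encodes a membrane-spanning glycoprotein of the nuclear pore complex, with control-hairpin cells, to measure the genome-wide change in expression after knockdown. Each group had 2 libraries, with TPM values, which are normalised for transcript length and library total, for 20226 listed genes. The shNUP210 libraries had 14564 and 14405 genes at 1 TPM or more, against 13920 and 13675 in the shCon libraries. The 100 most abundant genes took 37.6 and 38.1% of TPM in the shNUP210 libraries and 42.8 and 43.5% in the shCon libraries. Read depth is not kept in TPM and is unknown beyond the approximate worth of 1 fragment. On log2 values of the 10140 tested genes, the first principal component held 52% of the variance and separated the groups.

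NUP210 (ENSG00000132182, GRCh38 chromosome 3, 13316235 to 13420309, minus strand, protein-coding) was at 9.98 ± 0.18 TPM in the shNUP210 libraries and 30.05 ± 3.92 TPM in the shCon libraries (SD, n = 2 each). Both knockdown libraries (10.1 and 9.85 TPM) lay below both control libraries (32.8 and 27.3 TPM). The log2 fold change was -1.50 (SE 0.24), with a limma adjusted p of 0.043. That p exceeded 0.05 with no filter (0.129), with a filter of 1 TPM in 2 libraries (0.0781), without the mean-variance trend (0.0991) and when any library was left out (0.162 to 0.167). The NUP210 log2 fold change was -1.51 and -1.48 without shNUP210 replicate 1 or 2, and -1.37 and -1.62 without shCon replicate 1 or 2.

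After knockdown VIM and TAGLN rose, and APOA1 and SERPINC1 fell. VIM (chromosome 10, 17228259 to 17237593, plus strand), encoding the intermediate filament protein vimentin of mesenchymal cells, rose from 224 ± 27 to 1243 ± 77 TPM (5.55-fold, limma adjusted p = 0.0025). TAGLN (chromosome 11, 117199321 to 117204782, plus strand), encoding the actin-binding protein transgelin of smooth muscle, rose from 44.0 ± 9.2 to 449.8 ± 7.9 TPM (10.2-fold, adjusted p = 0.0029). APOA1 (chromosome 11, 116835751 to 116837950, minus strand), encoding the main protein of high-density lipoprotein, fell from 5099 ± 92 to 2059 ± 7.3 TPM (0.404 of the control mean, adjusted p = 0.0025). SERPINC1, encoding antithrombin, fell from 59.4 ± 6.4 to 10.8 ± 1.5 TPM (adjusted p = 0.013). These values are means ± SD with n = 2, and coordinates are GRCh38.

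By limma on log2(TPM + 1), 290 of 10140 genes passed an adjusted p of 0.05, 181 higher and 109 lower after knockdown, and 180 of them changed at least 2-fold (116 higher, 64 lower). At an unadjusted p under 0.05 there were 2469 genes. The direction split depends on the scaling: the median log2 fold change of all tested genes was +0.23 in TPM as deposited, and it was +0.0024 after trimmed-mean scaling, which called 328 genes, 76 higher and 252 lower. Upper-quartile scaling gave 66 higher and 279 lower, median-ratio scaling 77 and 250, and quantile normalization 87 and 116. Under all 5 scalings 154 genes were called, 55 higher and 99 lower. Of the genes named below, VCL, LAMC1, CLDN1, BAMBI, GADD45B and ID3 were called only in TPM as deposited. Quantile normalization ended the calls of APOA2, FTH1, PPL, COL1A2, ANKRD1, KCNJ8, HMGN1P38, RPS27P8 and PRR11-AS1, upper-quartile scaling that of FLNA, and the median-ratio, upper-quartile and trimmed-mean scalings those of LAMA5, FN1, PEG10, KRT8 and KRT18. Without the mean-variance trend limma called 0 genes, with 2290 at an unadjusted p under 0.05. No filter gave 15 calls, and a filter of 1 TPM in 2 libraries gave 57. There were 27 and 24 calls without shNUP210 replicate 1 or 2, and 11 and 4 without shCon replicate 1 or 2. All 290 genes kept the sign of their fold change in each setting that included them. Filters, the robust prior and the variance trend do not alter a fold, so for those settings the sign was fixed in advance. Median-ratio, upper-quartile and trimmed-mean scaling shift all folds by about the same amount. They moved the median to no lower than -0.044, while the smallest rise called was 0.362, so a change of sign was hardly possible. Fits without a library reuse the remaining libraries. The kept signs are therefore little evidence of robustness. Of the 290 genes, 109 overlap exons of another listed gene, among them LAMA5, VCL, DGAT1, SLC16A3, CEBPA and PEG10 below, and their reads may be shared with it. The scale understates the folds of low genes. The plot of fold change against abundance shows the shift of the median with level.

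**Figure D1:**
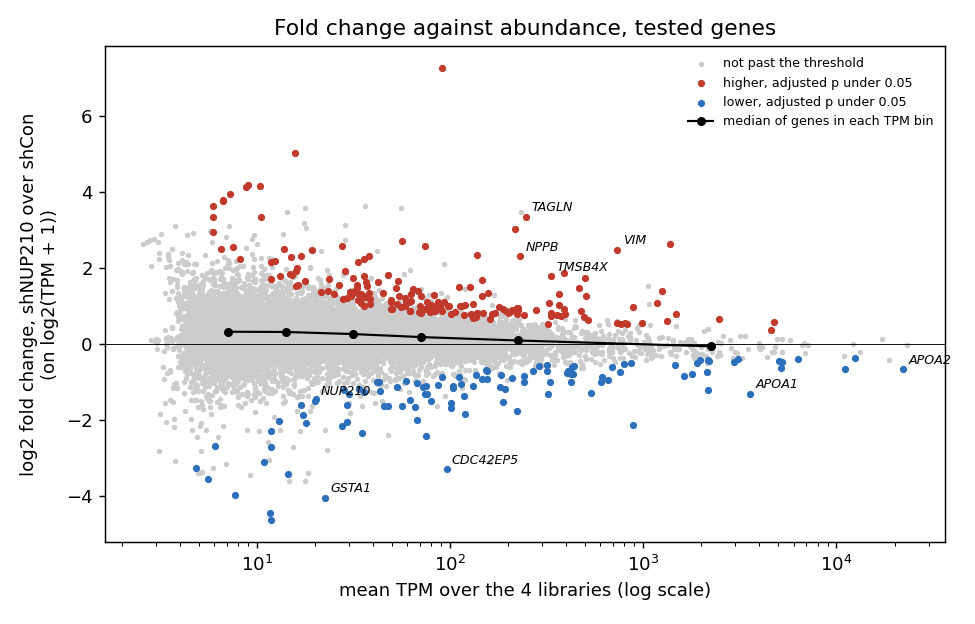
Log2 fold change of shNUP210 over shCon on log2(TPM + 1) against the mean TPM of the 4 libraries (log scale) for the 10140 tested genes, without XIST and TSIX. Red and blue points are genes higher and lower at an adjusted p under 0.05, and the black line joins the median fold change of each abundance bin, from 0.318 under 10 TPM to -0.0655 at 500 TPM and above.

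Among protein-coding genes without an overlapping partner, the highest folds were named after their values were seen. MATN3, a cartilage matrix protein gene, rose from 14.3 ± 2.9 to 98.7 ± 9.2 TPM (adjusted p = 0.0098). PROM1, encoding the progenitor surface protein CD133, rose from 7.29 ± 1.2 to 47.8 ± 1.7 TPM (adjusted p = 0.013). NPPB, encoding B-type natriuretic peptide, rose from 77.7 ± 3.4 to 385.8 ± 18.7 TPM (adjusted p = 0.0028). PPL, FLRT2, DIPK2A, CCN1 and FAM98A were the others, with log2 fold changes of 2.22 to 2.54. At the low end, CDC42EP5 (chromosome 19, 54465026 to 54473264, minus strand), an effector of the small GTPase CDC42, fell from 174.8 ± 15.1 to 17.2 ± 5.0 TPM (adjusted p = 0.0065). GSTA1, an alpha-class glutathione transferase of hepatocytes, fell from 43.0 ± 2.5 to 1.91 ± 1.7 TPM (adjusted p = 0.024). CES1, a liver carboxylesterase, fell from 20.4 ± 6.7 to 1.44 ± 0.092 TPM (adjusted p = 0.030). SERPINC1, CSF3R, GNG4, PRAP1 and SMIM1 completed the 8, with log2 fold changes of -2.35 to -1.87. With the filter of 1 TPM in 2 libraries, MATN3, PROM1, NPPB, CDC42EP5 and SERPINC1 stayed past the threshold and the other named genes of this group did not.

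The rule for all gene types named other transcripts. RN7SKP160 was at 34.9 and 28.3 TPM in the shNUP210 libraries and was listed at 0 in both shCon libraries. PPP1R35-AS1 (23.5 and 11.6 TPM), PRR11-AS1 (17.8 and 8.91 TPM) and RPS27P8 (17.6 and 9.0 TPM) were likewise listed at 0 in both shCon libraries. HMGN1P38, KCNJ8 and LINC02802 were higher by 3.35, 3.34 and 3.02 on the log2 scale. In the other direction, PJVK (22.5 and 25.0 TPM in shCon), TAB3-AS2 (34.4 and 12.4 TPM) and ATP6V1G2-DDX39B (19.7 and 11 TPM) were listed at 0 in both shNUP210 libraries. GATD1-DT and PARVB had log2 fold changes of -3.43 and -3.26. Several of these are pseudogenes, antisense RNAs or read-through genes whose reads the authors' counting could share with another gene, so their levels are uncertain. The same limit holds for VIM, whose exons overlap VIM-AS1, and TAGLN, whose exons overlap PCSK7, since the sources used here do not say that reads were counted by strand. Summed over both genes, VIM with VIM-AS1 was at 3617 ± 153 TPM against 606 ± 10.4 TPM, and TAGLN with PCSK7 at 578 ± 23.9 against 64.7 ± 7.2 TPM (SD, n = 2). TPM are normalised to each gene's own length, so these sums do not restore reads shared between the genes. VIM-AS1 itself had a mean of 1378 TPM over the 4 libraries, above VIM in either group (1243 and 224 TPM).

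Of the 40 gene lists tested, camera called 15 at a preset correlation of 0.01, 5 upward and 10 downward relative to all other genes. None of the 15 held with an estimated correlation, where adjusted p ranged from 0.435 to 0.597. With an estimated correlation camera uses the 2 residual degrees of freedom of this design, so it had little power for any list. Here and below, those adjusted p-values neither bear the calls out nor count against them. The preset correlation is an assumption that these libraries cannot check. By fry, which asks whether a list moves 1 way on balance and so takes in the upward shift of all genes, 5 of the 15 passed: hepatocyte secreted proteins, xenobiotic metabolism, amino acid metabolism, extracellular matrix and TGF-beta targets. List medians are given relative to the median of all tested genes, which the scaling moves.

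Hepatocyte secreted protein genes lay 0.95 below the median of all genes on the log2 scale (camera adjusted p = 5.3e-19, adjusted p = 0.435 with an estimated correlation). Of 27 tested members, 12 fell, 0 rose and 15 did not pass. Adjusted over the list alone, 17 fell and 1 rose, and after trimmed-mean scaling 15 fell. The list also holds ASGR1 and ASGR2, which encode subunits of a membrane receptor and not secreted proteins, and ASGR2 is among the 12 that fell (limma adjusted p = 0.030). APOA2, another high-density lipoprotein protein and the most abundant member, fell from 27180 ± 1499 to 17130 ± 316 TPM (adjusted p = 0.0098). SERPINA1, encoding alpha-1 antitrypsin, fell from 2676 ± 58 to 1610 ± 11 TPM (adjusted p = 0.0098). RBP4, the plasma carrier of retinol, was at 0.513 of the control mean (adjusted p = 0.0099). ALB, encoding albumin, was at 2494 ± 49 and 2479 ± 209 TPM, APOB at 149 ± 3.0 and 146 ± 14 TPM and APOE at 2914 ± 36 and 2714 ± 87 TPM in shNUP210 and shCon, and these did not pass (adjusted p 0.95, 0.90 and 0.33). TTR, encoding transthyretin, was at 418 ± 29 and 282 ± 9.5 TPM (adjusted p = 0.0501).

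Amino acid and urea metabolism genes lay 0.82 below the median of all genes (camera adjusted p = 4.9e-09, adjusted p = 0.435 with an estimated correlation), with 2 of 14 members lower, 7 lower adjusted over the list alone and 4 after trimmed-mean scaling. Both called members encode consecutive enzymes of the urea cycle: ASS1 fell from 85.7 ± 21.8 to 26.7 ± 6.9 TPM and ASL from 107.0 ± 1.9 to 42.4 ± 1.6 TPM. Xenobiotic and bile acid metabolism genes lay 0.56 below (camera adjusted p = 0.0012, adjusted p = 0.505 with an estimated correlation), and GSTA1 was the single called member of 10, with 2 lower adjusted over the list alone and 2 after trimmed-mean scaling. Complement and coagulation genes had 0 called members of 23 (camera adjusted p = 0.012, adjusted p = 0.505 with an estimated correlation); adjusted over the list alone, 2 were higher and 4 lower, and after trimmed-mean scaling 4 were lower. Of 21 liver transcription factors, the list was not called (camera adjusted p = 0.67), although CEBPA (522 ± 9.6 to 339 ± 11 TPM) and CEBPB (174 ± 15 to 98.1 ± 2.9 TPM) fell. HNF4A was at 153 ± 18 and 124 ± 7.2 TPM in shNUP210 and shCon and did not pass (adjusted p = 0.24).

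Lipid and stress-response lists also lay below the median of all genes. Abundant genes as a whole did so too, with a median log2 fold change of 0.0881 at 100 to 500 TPM and -0.0655 at 500 TPM and above. The median of the ribosomal protein list below was -0.136. Camera compares a list with genes of every level, so part of the displacement of lists of abundant genes may be this trend. That part was not tested. Fatty acid synthesis genes had 2 of 18 members lower, ACSS2, which makes acetyl-CoA from acetate (101 ± 18 to 30.8 ± 1.7 TPM), and DGAT1, a triglyceride synthesis enzyme (203 ± 3.4 to 106.5 ± 19.4 TPM), 5 lower adjusted over the list alone and 4 after trimmed-mean scaling (camera adjusted p = 0.00063, adjusted p = 0.505 with an estimated correlation). Cholesterol synthesis genes had 0 of 25 called (camera adjusted p = 0.0075, adjusted p = 0.505 with an estimated correlation) and 1 higher adjusted over the list alone, with 0 after trimmed-mean scaling. Glycolysis and hypoxia targets had 1 of 25 lower, the lactate transporter SLC16A3, adjusted over the list alone 4 higher and 7 lower, and after trimmed-mean scaling 5 lower (camera adjusted p = 0.016, adjusted p = 0.505 with an estimated correlation); their raw median (0.03) and mean (0.07) were above 0, while the test against all other genes pointed down. NRF2 targets, the antioxidant response genes, had 5 of 18 lower and 0 higher (camera adjusted p = 0.00046, adjusted p = 0.505 with an estimated correlation); adjusted over the list alone the counts were 5 lower and 1 higher, and after trimmed-mean scaling 5 lower. The ferritin subunits FTL (6306 ± 39 to 4055 ± 66 TPM) and FTH1 (13530 ± 340 to 8585 ± 447 TPM), the aldo-keto reductase AKR1C1 (73.1 ± 2.1 to 22.8 ± 0.21 TPM), NQO1 and TKT were those members. Cytosolic ribosomal protein genes had 6 of 53 lower, among them RPS2 and RPL13, 14 lower adjusted over the list alone and 16 after trimmed-mean scaling (camera adjusted p = 2.1e-09, adjusted p = 0.505 with an estimated correlation). Quantile normalization ended the camera calls of the ribosomal list (adjusted p = 0.10) and of the glycolysis list (0.13), and removal of the length and GC trend also ended that of the glycolysis list (0.0533). The lists of nuclear-encoded oxidative phosphorylation genes (1 of 43 higher, 0 lower) and of unfolded protein and integrated stress response genes (2 of 29 lower, 0 higher) were not called (camera adjusted p = 0.135 each), but after trimmed-mean scaling both were called downward (0.000872 and 0.0179), with 3 and 4 members lower. Adjusted over the list alone, 1 was higher in the first and 4 were lower in the second. In TPM as deposited, the camera adjusted p with an estimated correlation was 0.561 and 0.505.

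YAP and TEAD targets, genes induced by the transcriptional effectors of the Hippo pathway, had the largest upward displacement, 0.76 above the median of all genes (camera adjusted p = 0.00038, adjusted p = 0.505 with an estimated correlation). Of 13 tested members 5 rose and 0 fell, and 8 rose adjusted over the list alone. CCN1 rose from 12.5 ± 4.6 to 64.1 ± 2.8 TPM, CCN2 from 41.2 ± 3.4 to 100.3 ± 2.7 TPM and AMOTL2 from 20.7 ± 4.0 to 74.5 ± 11 TPM (adjusted p 0.027, 0.025 and 0.026), with ANKRD1 and GADD45B as the others. After trimmed-mean scaling 4 of the 13 rose. Extracellular matrix and adhesion genes lay 0.70 above (camera adjusted p = 0.00018, adjusted p = 0.505 with an estimated correlation), with 5 of 23 higher (COL1A2, LAMA5, LAMC1, VCL and FLNA) and 16 higher and 1 lower adjusted over the list alone. FLNA, encoding the actin cross-linker filamin A, rose from 130.7 ± 11.7 to 245.1 ± 0.24 TPM. TGF-beta targets had 4 of 15 higher (TAGLN, TGFBI, BAMBI and ID3) and 7 adjusted over the list alone (camera adjusted p = 0.00043, adjusted p = 0.505 with an estimated correlation). After trimmed-mean scaling 2 members each of the matrix and TGF-beta lists rose.

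The epithelial and mesenchymal list lay 0.53 above the median (camera adjusted p = 0.0075, adjusted p = 0.561 with an estimated correlation). The 5 members of 17 that rose were of both kinds: the mesenchymal genes VIM and FN1, the simple-epithelial keratins KRT8 and KRT18, and the tight-junction gene CLDN1. Adjusted over the list alone, 9 were higher and 2 lower. This added the epithelial gene DSP and the mesenchymal genes CDH2, MMP14 and SPARC as higher. The 2 lower were the epithelial claudin genes CLDN3 (8.9 to 2.51 TPM) and CLDN7 (8.24 to 0.965 TPM). KRT8 went from 3812 ± 110 to 5667 ± 66 TPM, and KRT18, whose exons overlap those of KRT8, from 1056 ± 51 to 1614 ± 41 TPM; after trimmed-mean scaling VIM was the 1 called member. The epithelial cadherin CDH1 was at 10.2 ± 3.0 and 9.31 ± 1.0 TPM and did not pass (adjusted p = 0.90). Oncofetal and progenitor genes were not called as a list (camera adjusted p = 0.65, pointing down against a median of 0.02 and a mean of 0.12) and moved both ways, with 3 of 16 higher and 1 lower. PROM1 rose, as did the cholangiocyte keratin KRT19 (66.6 ± 12 to 187.4 ± 7.0 TPM) and PEG10, the last not called after trimmed-mean scaling, while DLK1, an imprinted Notch-like ligand, fell from 343.9 ± 2.6 to 100.8 ± 6.2 TPM. Adjusted over the list alone, 4 were higher and 3 lower.

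**Figure D2:**
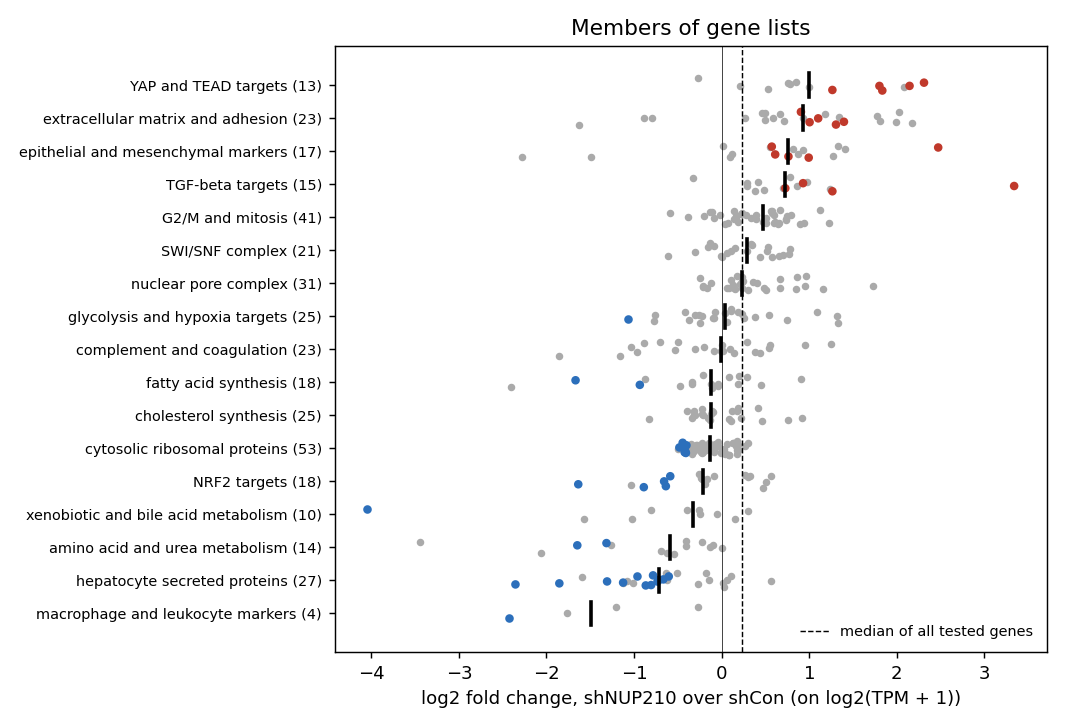
Log2 fold change of shNUP210 over shCon on log2(TPM + 1) for the tested members (number in brackets) of the 15 lists called by camera and of the nuclear pore and SWI/SNF lists. Each point is a gene, red if higher and blue if lower at an adjusted p under 0.05, the black bars are list medians and the dashed line is the median of all tested genes, 0.234; hepatocyte secreted proteins centre at -0.716 and YAP and TEAD targets at 0.998.

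Mitotic genes were called upward as a list (camera adjusted p = 0.041, adjusted p = 0.597 with an estimated correlation), with 0 of 41 members called and 4 higher adjusted over the list alone. That list call ended under trimmed-mean scaling (0.13) and after removal of the length and GC trend (0.26). Neither the 31 other nuclear pore genes (camera adjusted p = 0.38) nor the 21 SWI/SNF genes (camera adjusted p = 0.83) held a called member by limma. With 290 of 10140 genes called, lists of this size would hold few calls or none at the rate of all genes. Log2 fold changes of the pore genes ran from -0.25 for TPR (limma adjusted p = 0.62) to 1.73 for NUP42 (limma adjusted p = 0.057). The nuclear pore list passed fry (adjusted p = 0.024), which does not compare a list with other genes: its median log2 fold change of 0.23 was that of all genes (difference -0.0020), and it was -0.00547 after trimmed-mean scaling. SMARCB1, a core SWI/SNF subunit, was at 160.9 ± 3.1 and 144.6 ± 5.1 TPM in shNUP210 and shCon, a log2 fold change of 0.15 (SE 0.11, adjusted p = 0.43) that lay below 0 after median-ratio, upper-quartile and trimmed-mean scaling. EP300, a histone acetyltransferase, had a log2 fold change of 0.46 (SE 0.33, adjusted p = 0.43). MEF2C, a transcription factor, was below the filter, at 1.73 and 7.25 TPM in the shNUP210 libraries and 0.43 and 0.58 TPM in the shCon libraries.

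Markers of other cell types were examined beside these groups. Of 17 macrophage and leukocyte markers 4 were tested, and LYZ, encoding lysozyme, fell from 127.5 ± 4.2 to 23.2 ± 5.2 TPM (camera adjusted p = 0.00063, adjusted p = 0.505 with an estimated correlation; 2 lower adjusted over the list alone). LYZ shares exon sequence with the overlapping gene ENSG00000257764, and their sum was 356 ± 29 against 1576 ± 9.2 TPM, with the same limit as the sums above. The stellate and fibroblast list (camera adjusted p = 0.65) had 1 of 4 tested members higher, COL1A2, from 17.2 ± 1.2 to 47.0 ± 2.5 TPM, and 2 higher (COL1A1 and COL1A2) and 1 lower (BGN) adjusted over the list alone. The cholangiocyte list (camera adjusted p = 0.98) had 1 of 6 higher, KRT19, and 1 higher and 1 lower (EPCAM) adjusted over the list alone. Of 14 endothelial markers 1 was tested, EGFL7, at 60.0 TPM against 77.1 TPM in controls; it did not pass over all genes (adjusted p = 0.196) and was lower adjusted over the list alone, where it was the 1 gene.

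**Figure D3:**
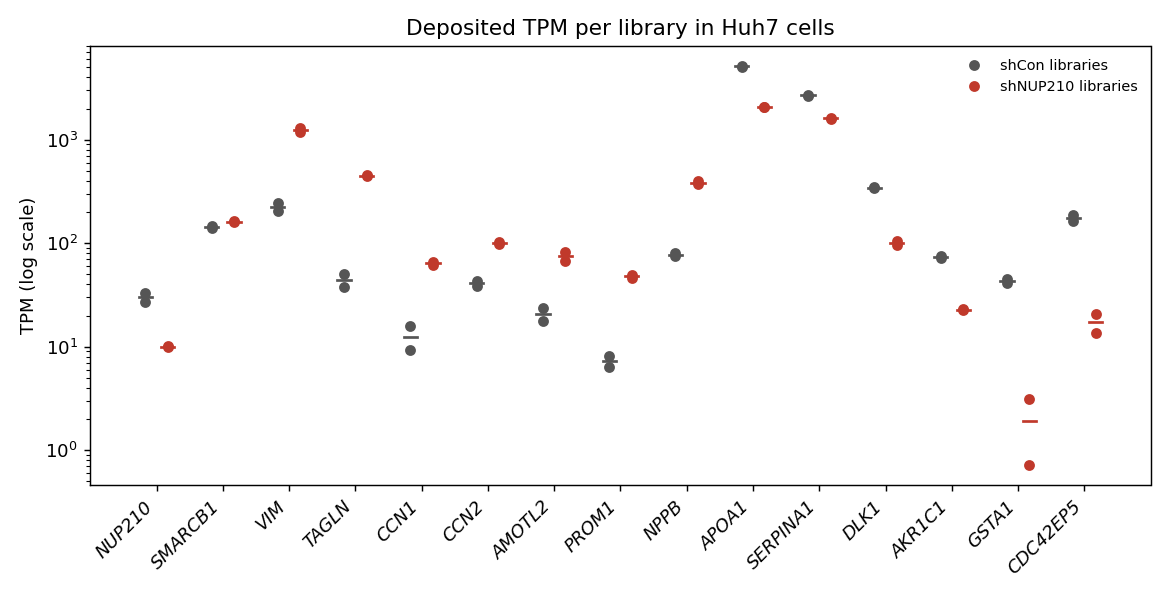
Deposited TPM (log scale) of 15 named genes in each of the 2 shCon (grey) and 2 shNUP210 (red) libraries, with a bar at each group mean. NUP210 lies at 10.1 and 9.85 TPM in the shNUP210 libraries and at 32.8 and 27.3 TPM in the shCon libraries, and SMARCB1 is the 1 gene shown that was not called.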

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

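The trimmed-mean and quantile scalings, the 1 TPM filter in 2 libraries, the fit without a variance trend and the pseudocounts of 0.1 and 5 were unplanned and chosen after seeing the data, though not after counts of calls; the length and GC correction was chosen after calls had been seen. All 290 called genes kept their direction in every setting that tested them, while the genes past the threshold changed, and with them the split between higher and lower. Filters, the robust prior, the variance trend, the replicate block and the adjusted p threshold leave folds as they are. For those settings the kept direction was fixed in advance and says nothing of robustness. Median-ratio, upper-quartile and trimmed-mean scaling shift all folds by about the same amount, to a median of -0.044 at the lowest. As the smallest rise called was 0.362, a change of sign was hardly possible there either. Fits without 1 library reuse the remaining libraries, so they are no independent check of direction. Against 290 calls (181 higher, 109 lower, 180 at least 2-fold), median-ratio scaling gave 77 higher and 250 lower, upper-quartile scaling 66 and 279, trimmed-mean scaling 76 and 252 and quantile normalization 87 and 116. So most calls were higher in TPM as deposited and lower under each of these scalings, which move the median of all genes from 0.23 to near 0. With no filter, 15 genes passed (10 higher, 5 lower, 15 at least 2-fold), and the NUP210 log2 fold change of -1.50 had an adjusted p of 0.129. With 1 TPM in 2 libraries, 57 passed (30 higher, 27 lower, 42 at least 2-fold; NUP210 -1.50, adjusted p 0.0781). Trimmed-mean scaling with that filter, the setting tried first, gave 157 (34 higher, 123 lower, 104 at least 2-fold). A filter of 1 TPM in all 4 libraries gave 320. Without the mean-variance trend, limma called 0 genes (0 higher, 0 lower, 0 at least 2-fold), with 2290 at an unadjusted p under 0.05 and NUP210 at -1.50 (adjusted p 0.0991). With the length and GC trend removed, 185 were higher and 61 lower; the cause was not tested. At an adjusted p of 0.01, 34 passed (19 higher, 15 lower, 28 at least 2-fold). A robust prior gave 256 calls, and pseudocounts of 0.1 and 5 gave 209 and 344.

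Leaving out 1 library, with the lone library of a group assumed to vary like the others, gave 4 to 27 calls (3 to 14 higher, 1 to 13 lower, 4 to 27 at least 2-fold), with 27 and 24 calls without shNUP210 replicate 1 or 2 and 11 and 4 without shCon replicate 1 or 2. The NUP210 log2 fold change ranged from -1.62 to -1.37, and its call ended whichever library was left out. Such a fit has fewer degrees of freedom, so this does not show that any 1 library decides the call. Libraries with the same number shared nothing visible (correlation of deviations 0.0231); with the number as a replicate block, 63 genes passed (31 higher, 32 lower, 47 at least 2-fold), and NUP210 stayed at -1.50 (adjusted p 0.0820). Of 40 named called genes besides NUP210, 16 passed with 1 TPM in 2 libraries, 35 after trimmed-mean scaling, 0 without the trend and 3 to 7 without a library. Of the 15 called lists, 0 held with an estimated correlation, which rests on 2 residual degrees of freedom and so had little power. By fry 5 held, with 12 after quantile normalization, 13 after the length and GC correction and 14 or 15 otherwise. The mitotic list was lost in the most settings. Other lists were gained: oxidative phosphorylation after median-ratio (adjusted p 0.00098), upper-quartile (0.000459) and trimmed-mean scaling (0.000872, with the 1 TPM filter 9.97e-05) and without shCon replicate 1 (0.0236), the unfolded protein and stress response after the same scalings (0.0188, 0.012, 0.0179 and 0.00616), G1/S genes with no filter (0.0126), and by fry nuclear pore (0.024), G1/S and nuclear lamina genes (0.0479 each). The glycolysis call ended after quantile normalization (adjusted p 0.132), after the length and GC correction (0.0533) and without shNUP210 replicate 1 (0.0544) or shCon replicate 1 (0.0757).

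Signs changed for 14 results that were called in none of the settings concerned, SMARCB1 and 13 gene lists, so no direction is read from them; the cause was not tested. The log2 fold change of SMARCB1 was -0.0884 after median-ratio scaling, -0.143 after upper-quartile scaling and -0.0938 after trimmed-mean scaling with either filter. List medians are relative to all genes. With no filter, nuclear pore genes were at 0.0332, nuclear transport receptors at -0.0533, oncofetal genes at 0.00425, growth factor receptor and PI3K genes at 0.0222, MEF2 and muscle genes at 0.136 and replication-dependent histones at -0.173. With 1 TPM in all 4 libraries, nuclear pore genes were at 3.28e-05, transport receptors at -0.0814, PI3K genes at 0.149, MEF2 genes at 0.0170 and histones at -0.146. With 1 TPM in 2 libraries, transport receptors were at -0.0846, oncofetal genes at 0.00849, interferon response genes at -0.00454, PI3K genes at 0.124, MEF2 genes at 0.107 and histones at -0.209. Trimmed-mean scaling with that filter gave transport receptors -0.104, homologous recombination genes 0.00537, PI3K genes 0.147, MEF2 genes 0.185 and histones -0.245. With a pseudocount of 5, nuclear pore genes were at 0.0228. After the length and GC correction, transport receptors were at -0.0616, SWI/SNF genes at -0.0545 and p53 targets at 0.0185. Without 1 library, the ranges were -0.00333 to 0.196 for nuclear pore genes, -0.0210 to 0.109 for transport receptors, -0.00676 to 0.0886 for SWI/SNF genes, -0.300 to 0.221 for homologous recombination genes, -0.215 to 0.118 for p53 targets, -0.0665 to 0.0365 for liver transcription factors, -0.179 to 0.0352 for fatty acid oxidation, -0.0311 to 0.603 for interferon response genes, -0.0554 to 0.210 for NF-kB genes, -0.242 to 0.0358 for PI3K genes and 0.00298 to 0.169 for MEF2 genes.

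The planned DESeq2, limma-voom and unrounded-count alternatives need counts and were not run. The unknown depth limits what can be said of genes near 0 TPM.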

Other observations

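The lists in this paragraph were written, and the tests of explanations in this part chosen, after the results had been seen, while the hepatocyte secreted protein list was fixed earlier. A list of 31 tested actin cytoskeleton and serum response factor (SRF) genes had 13 higher and 0 lower by limma, with 18 not passing, and 10 higher after trimmed-mean scaling. It left out called actin-binding genes such as COTL1, GSN and PARVB, with log2 fold changes of -1.68, -0.81 and -3.26, and FSCN1, which rose by 1.32. Metallothioneins, small metal-binding proteins, had 7 of 8 members higher and 0 lower, and 6 higher after trimmed-mean scaling. MT1H rose by 1.87 and MT2A by 1.07 on the log2 scale, but members are close paralogs among which reads can be shared. Of 11 imprinted genes 3 were higher and 1 lower, and of 15 tubulins and microtubule proteins 3 were higher and 1 lower. As these lists were written after the calls had been seen, the counts describe the listed genes and no list is taken as enriched.

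The hepatocyte secreted protein list was lower, with 12 of 27 members called lower and 0 higher, while VIM was higher. Dilution of Huh7 cells by cells of another type would lower hepatocyte mRNAs by 1 factor. Of the 27 members, 8 had a 95% interval wholly above the list median of -0.72 and 5 wholly below it. By chance 0.675 is expected on each side, if the spread between these libraries covers all variation. Judged by that spread, the members did not fall by 1 factor, which argues against dilution alone. The spread may be technical, so dilution together with variation between cultures is not excluded. After each library's length and GC trend was removed, the list median still lay 0.82 below that of all genes, against 0.95 below before (camera adjusted p 1.3e-19 after removal, at the preset correlation; the call before removal had an adjusted p of 0.435 with an estimated correlation), so that trend moved the displacement little. Stellate cells or fibroblasts were weighed as the source of the VIM rise of 1019 TPM, taken for VIM alone without the overlapping VIM-AS1. Of their 15 markers fixed in advance 9 are listed, while ACTA2, DCN, DES, POSTN, LRAT and FAP are not. The 9 rose by 38.1 TPM together, 3.74% of the VIM rise. The largest rise of their sum between any knockdown and control library, 50 TPM, lay below the smallest rise of VIM, 946 TPM. COL1A2 rose (48.8 and 45.2 against 16.4 and 18.1 TPM). Of the others, COL1A1 was at 18.9 and 7.55 against 1.25 and 3.8 TPM, LUM at 4.02 and 3.01 against 1.71 and 2.64 TPM, PDGFRB at 12.6 and 7.44 against 7.37 and 8.59 TPM, RGS5 at 4.96 and 2.09 against 2.99 and 0.69 TPM, BGN at 7.07 and 8.67 against 18.0 and 12.8 TPM, PDGFRA at 0.6 and 0.25 against 1.27 and 1.29 TPM, COL3A1 was at most 1.23 TPM and THY1 at most 0.5 TPM. Outside this sum, TAGLN (44.0 to 449.8 TPM) and the mesenchymal genes FN1 (266 to 453 TPM) and SPARC (23.3 to 62.7 TPM, not called) were also higher. Where such cells make collagen at about the level of vimentin, the collagen values argue against them as that source. The unlisted markers leave this incomplete, and a small number of such cells is not excluded. A hypothesis is that loss of NUP210 may lower part of the hepatocyte secretory program of Huh7 cells and raise YAP targets; no second hairpin or rescue is among these libraries, so an effect of the hairpin itself or of culture state is also open.

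Abundant mRNAs were lower and weaker mRNAs higher in the knockdown libraries. The median log2 fold change went from 0.318 under 10 TPM to -0.0655 at 500 TPM and above. The 100 genes most abundant in the control libraries, a choice that itself favours a lower share elsewhere, held 37.3% of TPM after knockdown and 43.1% in controls, which alone would raise all other genes by 0.141. That shift would be equal at every level, while genes under 10 TPM and genes of 50 to 100 TPM differed by 0.14 (bootstrap SE 0.0201). Genes near the filter of 5 TPM in 2 libraries could pass it through the knockdown libraries alone, which can widen that difference. Genes of 10 to 20 TPM, further from the filter, had a median of 0.312 against 0.178 at 50 to 100 TPM, with no SE computed. Before any length and GC correction, this argues against the shift as the whole cause. Length and GC bias stays open: the slope of fold change on abundance was -0.0476 before and -0.023 after that trend was removed, against -0.0029 and -0.0124 between replicates. The medians under 10 TPM, at 10 to 20 TPM and at 50 to 100 TPM were then 0.275, 0.293 and 0.257. Both effects together may explain much of the pattern, and with a single comparison they cannot be told apart from a change in RNA content.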
